A study of Homo sapiens with 38 samples.

How the data were processed

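ATAC-seq libraries were made from 100000 cells each with a 30-minute tagmentation and 10 PCR cycles, and were read as 50-base pairs, per the labels. The 38 libraries form 2 sets. One holds 22 untreated libraries of 11 lines, 2 per line, from library batches 1 and 3. The other holds 16 libraries of burb1, fiaj1, hehd1 and sojd3 from library batch 2, with 2 untreated and 2 CHR libraries per line, from independent experiments per the labels. CHR stands for chromatin restoration and includes another medium, matrix and IWP2, so treatment and culture cannot be separated.

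The submitters' processing notes name Bowtie2 2.4.4, SAMtools 1.21, MACS2 2.2.7.1, DESeq2 and the build GRCh38, without stating roles. The deposited tables hold, per the authors, log2 values of CPM, reads scaled to the library total, over a common set of peaks for each set, with 233473 and 225689 peaks. They were not divided by peak length, and it is not stated how peaks were pooled over libraries. A peak with no read holds the value of 0.9 reads. In all libraries 100% of values were whole reads within 0.02 reads, which gave the reads per peak and the library totals. These ran from 11.6 to 92.8 M (mega) reads in the first set, and in the second from 6.92 to 43.2 M untreated and from 16.0 to 48.3 M on CHR. Between 41.5% and 70.4% of reads fell in peaks in the first set. The median peak of a library held 7 to 91 reads. Replicate pairs correlated at r = 0.89 to 0.975 across peaks, and differed by 1.38 to 5.81 times the variance that counting alone gives. The smaller libraries therefore limit the precision of weak peaks most.

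Autosomal peaks were analysed (225695 and 217697), chromosome X was left out of the main fits and chromosome Y was never used, since both depend on the sex of the donor. Peaks were assigned to the gene with the nearest TSS within 50 kb, with positions from RefSeq and strand from the deposited tables. Of 28879 feature names 21022 were matched by symbol and 428 by an older symbol. For 2491 genes shorter than 10 kb without a known strand, both ends counted as a TSS. A promoter peak lay within 1 kb of a TSS. Gene accessibility was the mean log2 CPM of the peaks assigned to a gene.

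The shared CHR change was tested with limma 3.58.1 (empirical Bayes with a mean-variance trend) on the 8 means of line and treatment, with line as a term, and with Benjamini-Hochberg adjustment at 0.05. Changes in each line and the interaction of line and treatment were fitted on the 16 libraries, with 8 residual degrees of freedom. The differences between the 2 libraries of a group, by replicate number, correlated between untreated and CHR at 0.23, 0.09, 0.01 and 0.15 in burb1, fiaj1, hehd1 and sojd3, so the number was not used as a block in the main fit. Checked afterwards, they correlated between lines at 0.12 to 0.24 among untreated and at 0.09 to 0.45 among CHR libraries, and the share of reads in peaks rose on CHR in 4 of 4 lines in the second replicate and in 1 of 4 in the first. The lines with and without a CHR sample were compared on 11 line means, with the share of batch 3 libraries as covariate. Differences among lines were tested by a moderated F test on 22 libraries. Gene lists were tested with camera, with a preset inter-gene correlation of 0.01 and with an estimated one, and with fry. Promoter shares were compared with Fisher's exact test, two-sided. Peaks of both tables were matched by a reciprocal overlap of at least 50%. Work was done in R 4.3.3 with data.table (version 1.17.8) and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

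The fits were tested on simulated data, where changes of log2 1 and 2 were recovered for 49% and 100% of peaks in the shared comparison, 8% and 90% between the groups of lines, and 2% and 44% for CHR in a single line. Simulated CHR changes had the same size in every line, whereas the real ones differed between lines at 1303 peaks. Recovery of shared changes may therefore be lower in the real data. Named peaks were, before the data were examined, the 10 largest gains and 10 largest losses past the threshold with the same direction in 4 lines, 1 per gene, without unnamed gene models; 1 of them is not reported here. Up to 4 members per list were taken by adjusted p. This list rule was extended to the F test among lines. Zinc finger genes (by symbols that begin with ZNF, ZFP, ZSCAN or ZKSCAN), the 2 Mb windows and the genes named in them, and list members under promoter peaks alone were chosen after the values were seen.

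Alternatives fixed beforehand were other filters, centring, quantile normalization, chromosome X, no variance trend, a minimum change, library-level fits, a replicate block, left-out lines and replicates, other promoter and gene distances, and batch subsets. Chosen after seeing the data were fits without the 2 libraries under 10 M reads, reads thinned to 6.92 M, voom with quality weights, log2(CPM + 1), the share of reads in peaks as covariate and the promoter share within batch 1. No genome sequence was used, so motif tests and GC corrections were not run. A comparison of competent with noncompetent lines was not made, since neither labels nor tables assign lines to them.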

Results

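Accessible chromatin was mapped in human pluripotent stem cells of 11 lines in their usual culture, and in 4 of these lines before and after chromatin restoration (CHR). H1, H9 and HUES8 are embryonic stem cell lines, and the others are induced pluripotent lines. Values are log2 CPM (reads scaled to the library total) over peaks, and a change is CHR minus untreated, averaged over the 2 libraries of a line and treatment unless stated. CHR cells grew in StemFlex with 3 µM IWP2, an inhibitor of Wnt secretion, on laminin-521 for at least 8 passages, whereas untreated cells grew in Essential 8 on vitronectin. Every CHR difference below is therefore also a difference in medium and matrix.

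CHR was accompanied by shared gains and losses of similar size at distal sites, with more gains than losses when both replicates were used and more losses without the second replicate. The largest shared gain lay near FZD9, which encodes a Wnt receptor of the Frizzled family. This peak, on chromosome 7 at 73399279 to 73399840 (GRCh38), lay outside the gene, 33938 bases from its transcription start site (TSS). It rose by 3.56 ± 0.34 log2, from a low level of -2.58 to 0.99 (SE, n = 4 lines, limma adjusted p = 0.00113). The SE of a change, here and below, is limma's moderated one, which also draws on other peaks or genes. It does not measure the spread of the lines alone. Peaks near CDH5, the gene of the endothelial adhesion protein VE-cadherin, and inside POLA2, which encodes a subunit of DNA polymerase alpha, rose by 2.45 ± 0.29 and 2.4 ± 0.33. The largest shared loss lay in TBC1D23 on chromosome 3 at 100263115 to 100263458. This peak fell by 3.36 ± 0.51, from 0.15 to -3.21 (limma adjusted p = 0.00795). The SD of the 4 line changes was 1.04 near FZD9, 0.43 near CDH5 and 1.9 in TBC1D23. The promoter peak of CHCHD2, which encodes a mitochondrial protein, fell by 2.59 ± 0.52, from 2.72 ± 0.51 (SD, n = 4 lines) in untreated cells to 0.13 ± 2.46 on CHR. This loss differed between the lines (interaction adjusted p = 6.86e-06), with -5.67 in fiaj1 and -0.46 in hehd1, and without fiaj1 it was -1.57 and no longer called (adjusted p = 0.0615).

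Other gains that ran the same way in all 4 lines lay near GPRC5D-AS1, EFCAB14-AS1, PDE6B, CHL1-AS2, PGM2L1, MILR1 and LCE1E, with mean changes from 2.28 to 2.71. GPRC5D-AS1, CHL1-AS2 and LCE1E were reached at their promoters. Other losses lay near NCBP2AS2, ZNF44, TRIM26, CADPS, TMEM51-AS1, GK5 and BLNK, with mean changes from -3.33 to -2.38. The changes in hehd1 were often the smallest, for example -0.61 near TBC1D23 against -4.95 in sojd3, and -0.24 near TRIM26 against -4.04 in fiaj1. At CHL1-AS2 the gain was 5.74 in burb1 and 0.34 in sojd3, and the lines differed (interaction adjusted p = 6.06e-06). Without burb1 it was at 1.37 (adjusted p = 0.0695), and its call was also lost with quantile normalization (0.072) and without hehd1 (0.0789). LCE1E rose by 5.51 in burb1 and by 0.27 in sojd3; without burb1 it was at 1.2 (adjusted p = 0.176), and its call was also lost with median-centring and with quantile normalization (0.0576 and 0.0953). Without fiaj1 13 of the 19 peaks named here, all 9 losses among them, were no longer called, and without sojd3 8 were not. In fiaj1 each of these 9 losses was larger than its mean over the 4 lines, for example -5.15 against -3.33 near NCBP2AS2 and -4.11 against -2.46 near GK5. All 9 were therefore smaller without fiaj1, some of them only slightly. Without it the mean change was -3.21 at TBC1D23, -2.53 at CADPS, -2.51 at TMEM51-AS1 and -2.49 at TRIM26. The gain at GPRC5D-AS1 was then 2.79. Most of the named peaks were weak. When peaks of the lowest levels were dropped, 8 of the 19 named here stayed in the test, and none of these lost its call. The peak near FZD9 was among them, whereas those of CDH5, POLA2 and TBC1D23 were dropped. The POLA2 peak, for example, was at -3.07 untreated and at -0.67 on CHR. The smaller libraries limit the precision of such peaks most. A nearest TSS does not show which gene a peak acts on.

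**Figure D1:**
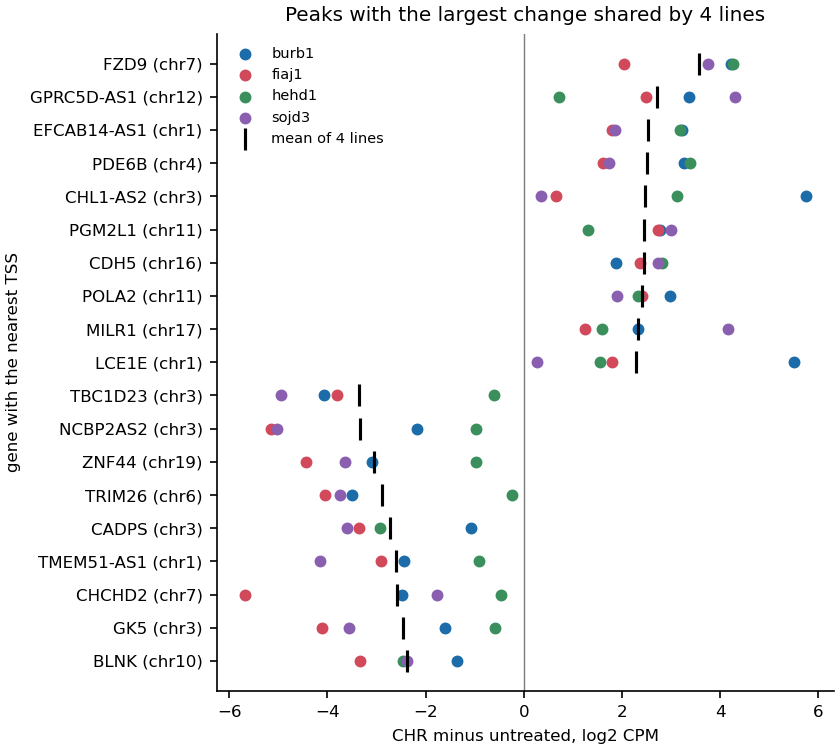
CHR minus untreated accessibility (log2 CPM, x axis) of 19 peaks named by the gene with the nearest TSS (y axis), each point the mean of 2 libraries per condition in 1 line and each bar the mean of 4 lines. All points of a peak lie on the same side of 0, and hehd1 is the line nearest to 0 in several, for example TBC1D23 (-0.61), TRIM26 (-0.24) and CHCHD2 (-0.46).

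Of 217697 autosomal peaks, 7898 changed on CHR (limma on line means, adjusted p under 0.05): 5539 were higher and 2359 lower, with median changes of 1.02 and -1.11, and the median of all peaks was 0.067. With quantile normalization 4125 were higher and 2780 lower, so the share of gains was 59.7% in place of 70.1%. In all 4 lines 7449 of the called peaks (94.3%) moved the same way, which a test on these line differences favours by itself. Promoter peaks, within 1 kb of a TSS, made up 2.73% of the gains and 2.12% of the losses against 7.04% of tested peaks (odds ratios 0.364 and 0.284, Fisher's exact test, p = 1.72e-46 and 1.83e-27). The count was 4280 without the 2 untreated libraries under 10 M reads (fiaj1 and sojd3, replicate 4). It was 194 without fiaj1, 229 without sojd3, 4491 without burb1 and 17133 without hehd1. Fits on the 16 libraries gave 15131, and 15790 with a replicate block. Without the second replicate of each condition the count was 1451, of which 220 were higher. Without the first it was 9799, of which 8791 were higher, so the balance of gains and losses differs between the replicates. It was 0 when limma's variance prior ignored the mean level (38838 at an unadjusted p under 0.05, lowest adjusted p = 0.134).

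At gene level, where all autosomal peaks within 50 kb of a gene were averaged, 20 of 19210 genes changed, 14 up and 6 down. EFCAB14-AS1 rose by 1.22 ± 0.13, PIBF1 by 1.09 ± 0.12 and NEDD1 by 0.93 ± 0.11 (SE, n = 4 lines, adjusted p = 0.0139 for each). PIBF1 and NEDD1 encode centrosomal proteins. The gain of NEDD1 comes from distant peaks, since it was 0.07 both within 10 kb and with promoter peaks alone (adjusted p = 0.855 and 0.942), and EFCAB14-AS1 was at 0.57 within 10 kb (adjusted p = 0.16). ALPG, an alkaline phosphatase gene and the only called member of the naive pluripotency list, fell by 0.89 ± 0.14 (adjusted p = 0.045), with -0.90, -0.60, -0.72 and -1.36 in burb1, fiaj1, hehd1 and sojd3, and with -0.37 at promoter peaks alone (adjusted p = 0.49). PSMG3, a proteasome assembly gene with 1 peak, fell by 1.84 ± 0.28 and KCNG3, a potassium channel subunit gene, by 0.79 ± 0.12. NAT14 fell by 0.84 ± 0.12 over all its peaks, and its change was 0 with promoter peaks alone. With quantile normalization, and without the 2 shallow libraries, 0 genes passed (3596 and 2873 at an unadjusted p under 0.05, limma), whereas 418 passed with promoter peaks alone. The changes behind these 2 counts of 0 were often about as large, with 1.10 and 1.22 for EFCAB14-AS1, 1.03 and 1.04 for PIBF1, 0.86 and 0.92 for NEDD1 and -1.93 and -1.79 for PSMG3, while ALPG was at -0.98 and -0.68.

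Of the 20 gene lists fixed before the data were examined, the HOX clusters were lower as a set, although none of their 37 measured genes passed alone. Their median change was -0.14 and 8 of 37 were above 0 (camera with a preset correlation, adjusted p = 1.94e-06); the adjusted p was 0.938 with an estimated correlation, and no list passed that test for the shared change. The fall was not seen in every line: the median was -0.11, -0.19 and -0.28 in burb1, fiaj1 and hehd1, but 0.09 in sojd3, with 23 of 37 genes above 0. In burb1, fiaj1 and hehd1 the list passed camera with the preset correlation (adjusted p = 0.000289, 1.01e-06 and 7.83e-05) but not with an estimated one (0.439, 0.34 and 0.346). By fry, which does not compare a list with other genes, the lowest adjusted p for the shared change was 0.474 for a shift in one direction and 0.00769 for changes in either. In single lines fry gave 0.0461 for the HOX clusters in hehd1 (lower) and 0.0205 for the loci recurrently aberrant in reprogrammed lines in burb1 (higher). The latter list was also higher by camera, in hehd1 with a preset and an estimated correlation (adjusted p = 0.000238 and 0.0383) and in burb1 with the preset one (0.016, and 0.191 estimated), and core pluripotency genes were lower in burb1 with the preset one (0.036, and 0.969 estimated). In hehd1 few of the aberrant loci carry the rise, with a median of 0.08 against a mean of 0.36, 10 of 16 above 0 and 0.158 by fry, and in fiaj1 and sojd3 camera put the list lower (unadjusted p = 0.0318 and 0.0171, adjusted 0.318 and 0.166). HOXA11 had a change of -0.52 ± 0.15 and HOXA7 of -0.54 ± 0.16 (SE, n = 4 lines, adjusted p = 0.159 for both). Targets of YAP and TEAD had 6 higher members and 1 lower member of 16 adjusted over the list alone, and 0 over all genes. ANKRD1 was at 0.64 ± 0.13 and CCN1, which encodes a matricellular protein, at 0.55 ± 0.12 in the list alone, and TGFB2 at -0.72 ± 0.23 (camera adjusted p = 0.0604, and 0.938 with an estimated correlation). CCN1 was at -0.07 with promoter peaks alone. With a replicate block, a fit that also counts 16 libraries in place of 8 means, ANKRD1, CCN1, LEFTY1, UTF1, PDGFRB, CGA, DPP6 and ZNF354C passed over all genes (adjusted p = 0.0452, 0.0395, 0.0494, 0.0388, 0.0118, 0.0427, 0.0237 and 0.0047).

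Among Nodal and Activin targets 2 of 14 members were higher and 1 lower adjusted over the list alone, with LEFTY1, an inhibitor of Nodal, at 0.59 ± 0.11 and GDF3, a ligand of the same pathway, at -0.45 ± 0.14. In the core pluripotency list UTF1 alone was lower, at -0.50 ± 0.11, and the primordial germ cell list, which shares UTF1, also had 1 lower member. PDGFRB, at 0.99 ± 0.18, was the only higher member of the fibroblast list. The amnion and trophectoderm list had 1 higher member, CGA at 0.60 ± 0.15, and 1 lower, TP63 at -0.45 ± 0.12. Loci recurrently aberrant in reprogrammed lines had 2 higher members and 1 lower, with CAT at 0.54 ± 0.12 and ZNF354C at -1.04 ± 0.19 (-0.08 with promoter peaks alone). No member passed in the lists of anterior epiblast and neurectoderm, posterior epiblast and primitive streak, canonical Wnt targets, BMP targets, FGF and ERK targets, primed and formative pluripotency, definitive endoderm, neural crest and placode, imprinted genes, HDAC and Polycomb machinery or housekeeping genes, even over the list alone. Among them FGFR3 was at 0.41 ± 0.14, MSGN1 at -0.30 ± 0.12, MYC at 0.25 ± 0.12, ID3 at 0.34 ± 0.12, DUSP6 at 0.41 ± 0.12, SALL2 at 0.35 ± 0.10, SOX17 at 0.35 ± 0.12, SOX9 at 0.33 ± 0.11, ZDBF2 at -0.47 ± 0.13, CBX7 at 0.42 ± 0.14 and PSMB2 at -0.26 ± 0.11.

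The lines also changed in different ways, most visibly at zinc finger genes. ZNF471 on chromosome 19, measured by 1 peak, was at -1.69 in untreated burb1 and rose by 6.22 in that line. It fell by 7.19 in fiaj1 and by 3.81 in sojd3, with 0.26 in hehd1 (moderated F test of the interaction, adjusted p = 6.45e-12). That test rests on the spread between the 2 libraries of a line and treatment. Whether the CHR libraries of a line come from separate derivations was not established, so differences between derivations may not be covered. ZNF208 rose by 5.79 in burb1 and fell by 6.34 in fiaj1. ZNF558 fell by 6.26 in sojd3 and was at 2.95 in hehd1. Of the zinc finger genes called in a line, 15 of 18 were higher in burb1 and 7 of 7 in hehd1, while 33 of 34 were lower in fiaj1 and 43 of 44 in sojd3. Under quantile normalization these directions held, with 17 higher and 5 lower in burb1, 14 and 0 in hehd1, 1 and 56 in fiaj1 and 3 and 86 in sojd3. The counts fell without the shallow libraries, to 28 in fiaj1 and 20 in sojd3, and with thinned reads, to 13 and 15, all of them lower.

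Zinc finger genes made up 40 of the 160 genes whose CHR change differed between lines, against 441 of 19210 tested (odds ratio 15.5, Fisher's exact test, p = 3.32e-30), and 34 of the 40 lay on chromosome 19. None of the 20 genes with a shared change was a zinc finger gene. With 2.3% of tested genes in the family, 0 of 20 does not set the shared change apart. A peak in ZNF44 is among the named shared losses. This group was chosen after its values were seen. In a check of identity written beforehand, 9 of the 16 libraries correlated best with their own line among the 11 lines of the other set, namely 7 of 8 untreated and 2 of 8 CHR libraries. In forms tried after that result, 14 did among the 4 lines given CHR, and 14 over peaks in which 1 line lies apart. The form chosen last, on isolated peaks of that kind, placed 16 of 16 and does not settle the identity. Of all peaks in hehd1 that were called, 50 of 266 lay on chromosome 19, all of them higher, where 3% of tested peaks lie.

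**Figure D2:**
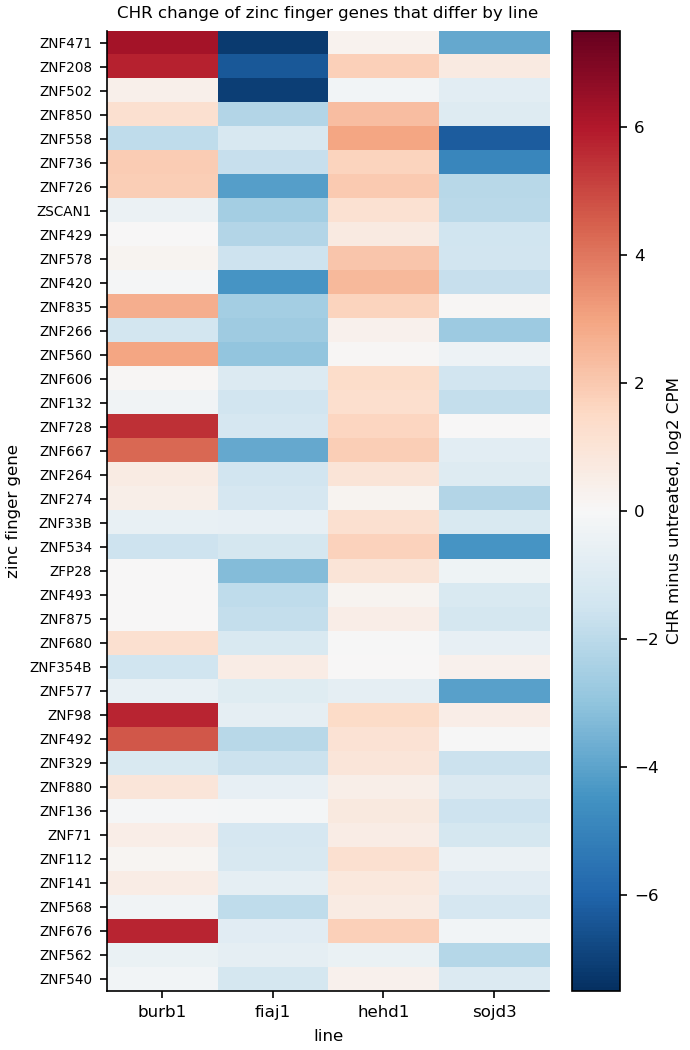
CHR minus untreated accessibility (log2 CPM, colour) of the 40 zinc finger genes (y axis) whose change differed between the lines (x axis), ordered by the interaction p. Each cell is the difference of the means of 2 libraries. ZNF471 ranges from 6.22 in burb1 to -7.19 in fiaj1.

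Accessibility changed over whole domains, mainly in single lines. Whether copy number changed in these domains was not tested. An exchanged library, left open by the identity check above, could also give a change to the level of other lines. In burb1, the first 4 Mb of chromosome 3, which hold the contactin genes CNTN6 and CNTN4, gained accessibility at 111 of 187 peaks and lost it at none. The median level of these peaks in burb1 was -3.93 untreated and -0.61 on CHR, close to the -0.57 of untreated hehd1 and the -0.54 of untreated sojd3. In the separate set of untreated libraries burb1 was again low, at -4.58, where the other 10 lines lay between -1.12 and -0.28. CNTN6 rose by 3.94 ± 0.33 (SE, n = 2 libraries per condition, limma adjusted p = 1.02e-07) and CNTN4 by 3.68 ± 0.27 in burb1. In fiaj1 the opposite was seen on chromosome 10 from 106 to 108 Mb, which holds SORCS1, a sortilin-family receptor gene: 66 of 93 peaks were lower and none higher, and the median level went from -1.11 to -4.38. In the separate set untreated fiaj1 was already the lowest of the 11 lines there, at -2.18, with the others between -1.25 and -0.36. No other group of either set, each of 2 libraries, was below -2.18. An exchange of whole groups would therefore not give the -4.38 of fiaj1 on CHR. Levels of single libraries were not compared there, so an exchange of single libraries stays open. SORCS1 fell by 3.38 ± 0.24 in fiaj1, with 0.17, -0.22 and -0.23 in burb1, hehd1 and sojd3.

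On chromosome 20 from 42 to 44 Mb, around the phosphatase gene PTPRT, 2 lines diverged. Of 133 peaks 23 were higher in burb1 and none lower, while 41 were lower in fiaj1 and none higher. In the separate set these were also the lowest untreated lines, at -1.59 and -1.28. PTPRT itself rose by 1.53 ± 0.25 in burb1 and fell by 3.06 ± 0.25 in fiaj1 (interaction adjusted p = 2.92e-07). In hehd1 the genes that rose included the olfactory receptor gene OR1N2, by 4.56 ± 0.37, and the cell adhesion genes CEACAM7 and CEACAM5, by 2.90 ± 0.28 and 2.60 ± 0.28. OR1N2 fell by 3.54 in fiaj1 and by 2.12 in sojd3. These regions and genes were chosen after their values were seen.

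**Figure D3:**
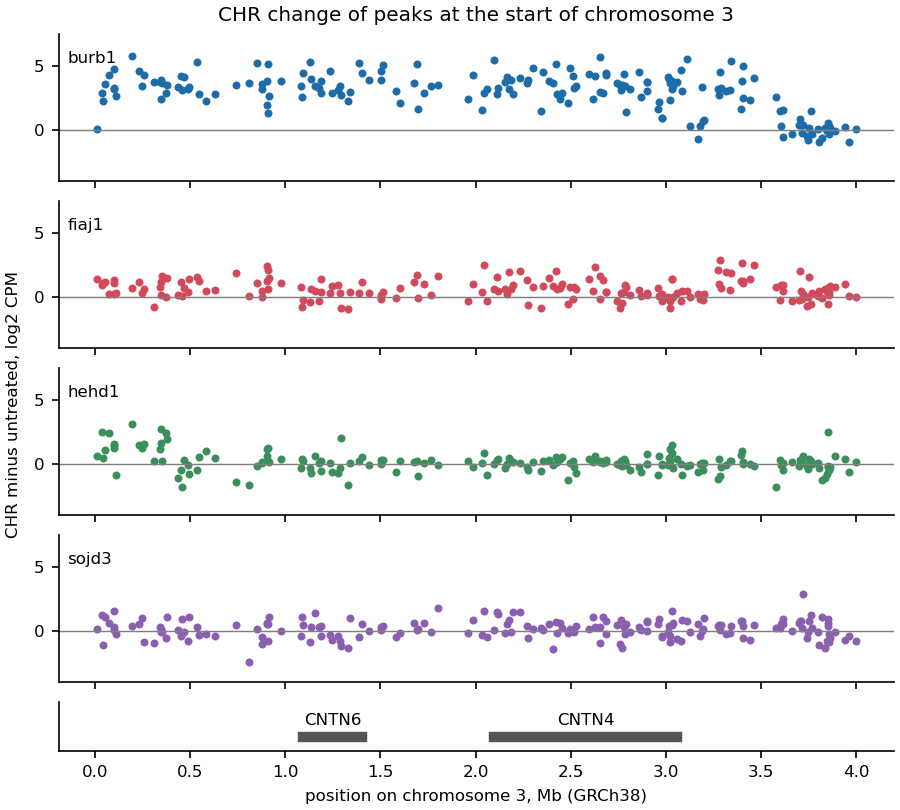
CHR minus untreated accessibility (log2 CPM, y axis) of 187 peaks in the first 4 Mb of chromosome 3 (x axis, Mb, GRCh38) in each line, with the extents of CNTN6 and CNTN4 as bars. The burb1 points lie mostly above 0 up to beyond CNTN4, with 111 peaks called, against 14 in fiaj1, 1 in hehd1 and 1 in sojd3.

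The number of peaks called per line ran from 266 in hehd1 (258 higher, 8 lower) through 1192 in burb1 (724 and 468) to 6237 in fiaj1 (4351 and 1886) and 6309 in sojd3 (3656 and 2653). The median change of all peaks was 0.058, 0.185, -0.077 and 0.106 in burb1, fiaj1, hehd1 and sojd3, so the splits are partly relative to that shift. With quantile normalization 4199 peaks were higher and 4222 lower in fiaj1, 5087 and 4811 in sojd3, 1035 and 965 in burb1 and 346 and 9 in hehd1. Median-centred values gave 3362 and 2876 in fiaj1 and 3641 and 3745 in sojd3, so the excess of gains in these 2 lines depends on the scaling. The CHR change differed between the lines at 1303 peaks (moderated F test of the interaction). Across peaks, which are not independent replicates, the changes of fiaj1 and sojd3 were the most alike (Pearson r = 0.47) and those of hehd1 the least (0.11 to 0.17). Both shallow untreated libraries belong to fiaj1 and sojd3: without them the counts were 702 (290 higher, 412 lower) and 1605, with 1482 in burb1 and 308 in hehd1, so burb1 then exceeds fiaj1.

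**Figure D4:**
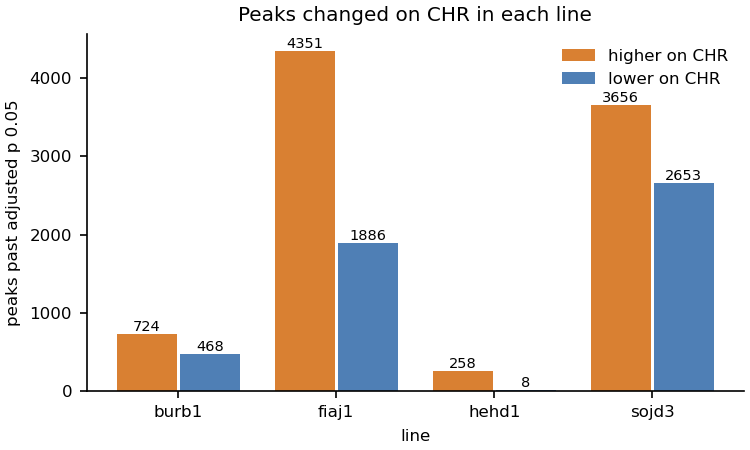
Number of autosomal peaks (y axis) past an adjusted p of 0.05 for CHR against untreated in each line (x axis, 2 libraries per condition), with orange bars for higher and blue bars for lower peaks. The bars reach 4351 in fiaj1 and stay at 258 and 8 in hehd1.

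Untreated lines differed by several log2 units at single loci. ZIM2, an imprinted gene on chromosome 19 measured by 1 peak, was at 4.99 in H1 and 5.80 in H9, and between -0.06 and 0.78 in the other 9 lines (adjusted p = 5.07e-13). TMEM132D was at -3.45 in kolf2 and between -0.74 and 1.34 elsewhere. TCERG1L lay between -3.61 in hehd1 and 1.36 in H9, and DPP6, which encodes a potassium channel partner, between -4.91 in hehd1 and 1.41 in H1. Loci recurrently aberrant in reprogrammed lines differed at 13 of 16 measured genes, HOX genes at 27 of 35, Nodal and Activin targets at 10 of 14 and canonical Wnt targets at 5 of 22, against 8809 of all 19256 genes (45.7%).

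Housekeeping genes, the control list, differed at 11 of 21, with VCP at 4.21 to 5.30. The lower values were those of deyz2, feec2 and cuhk2, whose libraries are all of library batch 3. In that batch 54.9% ± 7.96 of reads fell in peaks (SD, n = 8 libraries) against 67.0% ± 2.31 in batch 1 (n = 14). Of 225695 peaks, 91797 (40.7%) differed among the 11 lines (moderated F test, 2 libraries per line), and 53656 (23.8%) among the 6 lines with both libraries in batch 1. Promoter peaks were over-represented among the former (13.4% against 6.78% of tested peaks, odds ratio 6.84), but the odds ratio was 0.927 with quantile normalization and 0.669 within batch 1, so its direction reversed.

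The 4 lines that were also given CHR were set against the other 7, since the labels do not state which lines are competent to form organoids and no comparison by competence was made. No peak and no gene differed between these 2 groups (limma, library batch as covariate, 8144 of 225695 peaks and 597 of 19256 genes at an unadjusted p under 0.05). TGFB2 was 0.91 ± 0.29 higher in the lines with a CHR sample, NODAL 0.46 ± 0.20 and LEFTY2 0.43 ± 0.19 (SE, n = 11 lines, adjusted p = 0.9996 for each). Adjusted over the list alone, 2 of the 16 recurrently aberrant loci were lower, TAFA5 at -0.76 ± 0.16 and PTPRT at -1.11 ± 0.26, and none over all genes. PTPRT was at 0, -0.33 and 0.67 in burb1, fiaj1 and hehd1. In sojd3 it was at 1.52, inside the 1.08 to 1.56 of the lines without a CHR sample. Nodal and Activin targets were higher as a set with camera's preset correlation (adjusted p = 0.0356), but with an estimated correlation the adjusted p was 0.974. The levels of the 2 groups did not overlap at 983 peaks, or 0.44%, where chance gives 0.61%.

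Across 173592 peaks matched between both tables, the CHR change correlated with the level of the lines without minus that of the lines with a CHR sample (Spearman rho = 0.322, Pearson r = 0.328 across peaks, which are not independent). Within library batch 1 rho was 0.246. Without the batch covariate it was 0.156, and 45 of 100 random choices of 4 of the 11 lines gave a value as high, with a range from -0.50 to 0.528.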

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

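The test of the likeness of fiaj1 and sojd3 and the 3 later forms of the check for mislabelled libraries were chosen after the results they measure were seen, and zinc finger genes were taken up as a group after their values were seen. The CHR change differed between the lines at 1303 peaks and 160 genes by the interaction test, 40 of these being zinc finger genes. Of the named peaks reported here the interaction was past the threshold near CHL1-AS2 (adjusted p = 6.06e-06), LCE1E (0.0184), NCBP2AS2 (0.0305), CHCHD2 (6.86e-06) and GK5 (0.0031). In 3 of 43 groups of 4 line values 1 line lay far from the rest, where chance gives about 1 in 20: hehd1 near PGM2L1 with a change of 1.31, near TRIM26 with -0.24, and for THEM6 with 0.49.

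The first pattern is the shared change on CHR. Thinning all libraries to the same total of reads, of which 49.0% to 69.0% lay in peaks before it, kept at least 98.4% of the median change of gains and losses, and adding the share of reads in peaks kept at least 93.6%, so neither could be the whole cause. The 32 splits of the 8 line means that can be fitted make 20 distinct fits, too few for a share under 0.05. In 2 of these, the real one included, at least the 7898 peaks were called, with 16222 in the other, and for genes it was again 2, with 20 against 616. Counted as splits, as planned before equal fits were merged, these were 3 of 32, a share over 0.05. That other fit is CHR against untreated in fiaj1 and sojd3 only, a structure of the samples that holds part of the effect under test. Among the 8 splits that part every line the highest other gave 1 peak and 0 genes. CHR and the culture change stay confounded, so either may be the source.

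The second pattern is the opposite movement of zinc finger genes. Shallow libraries are argued against, since at least 95.9% of the median fall in fiaj1 and sojd3 was kept without them, and so is copy number, since neighbouring peaks within 200 kb had median changes of 0.12 and -0.03 (at most 2.1% of the fall) against -1.76 and -1.37 for the genes. A mislabelled library stays open: in the test written beforehand 9 of 16 libraries correlated best with their own line (7 of 8 untreated, 2 of 8 CHR), which is what mislabelling could give. Of 3 further forms, tried after that result, 2 placed 14 of 16 and the last, on isolated peaks in which 1 line lies apart, placed 16 of 16, so the full score is that of the form chosen last and does not settle it. The same holds for domains that went to the level of other lines, such as the first 4 Mb of chromosome 3 in burb1, from -3.93. On CHR fiaj1 was at -4.38 on chromosome 10 (106 to 108 Mb) and at -2.58 on chromosome 20 (42 to 44 Mb). All other groups of both sets were at -2.18 and -1.59 or above. This argues against an exchange of whole groups for these domains of fiaj1. These levels are each taken over 2 libraries, so an exchange of single libraries stays open. The pattern may be a difference between lines in the response to CHR or its medium, but this is a hypothesis.

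The third pattern is the likeness of fiaj1 and sojd3, the lines with the shallow untreated libraries. Their changes correlated at 0.47 across peaks with all libraries and at 0.47 without those 2, so these libraries could not account for it alone. Both lines called 1940 peaks, 1932 of them in the same direction, where independence gives 96.1 in the same direction. Other pairs exceeded independence by this measure as well. For burb1 and fiaj1 250 of 316 shared calls ran the same way, against 18.5 by independence. For burb1 and sojd3 it was 286 of 329 against 17.9, and for burb1 and hehd1 46 of 57 against 0.9. With 15 of 60 against 5.2 for fiaj1 and hehd1, and 27 of 59 against 4.4 for hehd1 and sojd3, most shared calls ran in opposite directions. The excess alone therefore does not mark fiaj1 and sojd3. With reads thinned to the lowest total the correlation was 0.33, above the 0.22 of burb1 and sojd3, the next highest. No biological explanation was tested.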

How the results depend on the processing

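For CHR against untreated, 7898 peaks became 6868 to 9799 when peaks of the lowest levels were dropped, libraries were median-centred or quantile normalized, chromosome X was added, log2(CPM + 1) was used or replicate 1 was left out. The count was 0 without the variance trend, where the prior carried 3.93 in place of 11.93 degrees of freedom, 4396 with a minimum change, 15131 on 16 libraries, 24429 with voom, 12074 with the share of reads in peaks, 4280 without the libraries under 10 M reads and 4103 thinned. Leaving out single lines gave 194 to 17133 (4491 without burb1, 194 without fiaj1, 17133 without hehd1, 229 without sojd3), and leaving out replicates gave 1451 (mostly losses) to 9799 (mostly gains). Fewer samples alone would not give such different counts, since each of these fits left out 1 line. A fit that compared CHR with untreated in fiaj1 and sojd3 only called 16222 peaks, so the count leans on these 2 lines. Why the lines and the replicates differ was not tested. The share of reads in peaks rose on CHR in 4 lines in the second replicate and in 1 in the first. With that share as covariate on 16 libraries 57.3% of called peaks were gains, against 65.1% without it. The median change of all peaks was then 0.026 against 0.067. Of the called peaks 4073 were also called without the shallow libraries and 3443 after thinning. Per line, quantile normalization gave 2000 peaks in burb1, 9898 in sojd3 and 2200 for the interaction. Without the shallow libraries there were 702 in fiaj1 and 1605 in sojd3, against 1482 in burb1. Thinned reads gave 503, 1608, 127 and 2392 in burb1, fiaj1, hehd1 and sojd3 and 527 for the interaction, so depth limits these counts. With a replicate block there were 15790 shared peaks, 2346, 14306, 629 and 12347 per line, 3839 for the interaction, 316 genes, and 1 peak between the groups of lines. The 16 libraries without the number gave a similar count of shared peaks (15131), and duplicateCorrelation without it also gave 1 peak between the groups, whereas the counts per line and for the interaction move with the number itself; why was not settled. Genes changed on CHR numbered 418 with promoter peaks alone, 314 within 10 kb, and 0 with quantile normalization or without the shallow libraries. Lists past camera's preset correlation rose from 1 to 2 in the first 2 of these (adding loci recurrently aberrant in reprogrammed lines, and YAP and TEAD targets) and with quantile normalization (YAP and TEAD targets), but none passed with an estimated correlation (adjusted p = 0.996, 0.971 and 0.878). For NAT14 the promoter value was 0, for AMOTL2 -0.05 and for CCN1 -0.07, opposite to or without the change over all peaks, and little was left of it for NEDD1 (0.07, also within 10 kb), THEM6 (0.07), ZNF354C (-0.08), ARRB2 (-0.11) and ALPG (-0.37). Between the groups of lines the count was 0 except for 1 with HPSI lines only, with duplicateCorrelation, without hehd1 or without HUES8, and 2 without kolf2 or without sojd3, a range of 0 to 2. Among lines 53656 peaks differed within batch 1, and the promoter odds ratio reversed to 0.927 with quantile normalization and to 0.669 within batch 1; the cause was not tested. Among alternatives fixed beforehand, named peaks kept direction and call in 196 comparisons and direction alone in 53. Motifs and all GC corrections, also with the replicate block, were not run for lack of a genome. The fits without shallow libraries, thinned, with voom, log2(CPM + 1), the share of reads in peaks and promoters within batch 1 were chosen after seeing the data.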

Other observations

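The genes and regions named here and the test of the spread between lines were chosen after their values were seen. With promoter peaks alone, an alternative in which 418 genes passed, several members of the lists changed. ANKRD1, a target of YAP, rose by 1.93 ± 0.21 (SE, n = 4 lines, adjusted p = 4.82e-12), with 1.40, 3.03, 1.01 and 2.28 in burb1, fiaj1, hehd1 and sojd3. In the core pluripotency list 3 of 21 promoters fell, DPPA2 by 0.89 ± 0.13, UTF1 by 0.62 ± 0.14 and GDF3 by 0.45 ± 0.13, the latter with 0.05 in hehd1. TCL1A, a germ cell gene, rose by 0.68 ± 0.13, and APLNR, the apelin receptor gene, by 0.59 ± 0.17. MEG3, a maternally expressed imprinted RNA, rose by 1.03 ± 0.24 on average but by 3.41 in burb1 against 0.10 to 0.44 in the others. DPP6 stood at 5.12 in burb1, 3.26 in fiaj1, 0.47 in hehd1 and -0.03 in sojd3. The adjusted p of ANKRD1 over the other settings ran from 0.0205 within 10 kb to 0.192 without the shallow libraries.

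Other domains changed most in 1 line, but not always in it alone. In burb1 60 of 281 peaks were higher between 2 and 4 Mb of chromosome 1, where PRDM16, a zinc finger regulator of brown fat, rose by 3.46 ± 0.23 and TTC34 by 2.96 ± 0.46; 22 peaks were called there in fiaj1 and 24 in sojd3, with medians of 0.51 and 0.29 against 0.51 in burb1. In fiaj1 32 of 87 peaks were lower between 6 and 8 Mb of chromosome 16, in RBFOX1, where 11 were called in burb1 and the median of sojd3 was -0.67. In sojd3 18 of 58 peaks were lower between 42 and 44 Mb of chromosome 9, where CNTNAP3B fell by 3.28 ± 0.50. Among untreated lines 298 of 442 zinc finger genes differed (67.4%, against 45.2% of other genes; odds ratio 2.50, Fisher's exact test, p = 1.89e-20).

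Whether lines become more alike on CHR was not settled. The SD over lines was lower on CHR at 62.6% of peaks as deposited and at 60.7% without the 2 shallow libraries, but at 54.2% after thinning, which also adds counting noise to both conditions. Published reports name HHLA1, ABHD12B and C4orf51 as loci hypomethylated in induced lines that differentiate poorly. Of these HHLA1 and C4orf51 were measured here, and 0 of the 2 fell in at least 3 lines. The outcome set beforehand as speaking against a closing on CHR, fewer than 2 of the 3 loci falling in 3 or more lines, was therefore met. Both loci fell in 2 lines. However, rises of 0.01 (C4orf51 in sojd3) and of 0.26 and 0.12 (HHLA1 in fiaj1 and hehd1) lie within the SE of 0.30 and 0.34. That limit was not part of the rule, and with it the count could not decide. C4orf51 rose by 0.75 ± 0.30 in hehd1.

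Along the main axis of the 7 untreated lines without a CHR sample (33.7% of their variance), it was tested whether CHR moved all 4 lines the same way, and 3 of 4 moved in the positive direction. The shifts were 80.6 in burb1, 158.1 in fiaj1, -12.2 in hehd1 and 118.8 in sojd3, with gaps between untreated replicates of 49.7, 70.1, 34.3 and 10.3. The outcome set beforehand as speaking against such a movement, changes that do not share a sign, was therefore met. However, the CHR libraries of hehd1 lay at -27.8 and 76.8, and its shift is within its gap between untreated replicates. That limit was not part of the rule for this outcome. With it the sign of hehd1 is uncertain and the test could not decide. The untreated positions in the other set were 120.9 for H1, 111.3 for kolf2, 84.6 for hehd1, 83.6 for H9, 60.3 for burb1, -1.9 for deyz2, -42.6 for cuhk2, -47.5 for sojd3, -56.1 for fiaj1, -77.9 for HUES8 and -193.4 for feec2. Among the 7 lines the axis also followed library batch. The lines with batch 3 libraries (HUES8, cuhk2, deyz2 and feec2) all lay on the negative side. From batch 1 libraries alone, where HUES8 has 1, the axis set HUES8 (-206.6) apart from H1, H9 and kolf2 (69.3, 73.2 and 64.1). The shifts on that axis were 84.6 in burb1, 105.3 in fiaj1, -18.8 in hehd1 and 117.2 in sojd3.

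For the lines with and without a CHR sample 0 peaks and 0 genes were called, a count that all 100 of 100 splits of the 11 lines into 4 and 7 reach by definition, so these splits say nothing about chance. The highest other split gave 4603 peaks and 360 genes, and what separates its groups of lines was not tested.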
